A study of Mus musculus with 7 samples.

How the data were processed

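Bulk RNA sequencing of 7 whole tumors was used, 4 from untreated and 3 from vaccinated mice, with groups and mouse numbers taken from the sample titles. Per the labels' protocols, RNA with an integrity number above 7 was extracted from tumor fragments, 500 ng was enriched for polyadenylated RNA, and libraries were made with random priming. Whether the libraries kept strand, and whether counting used it, was not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene ID for the 7 tumors, not normalized by the authors. STAR and featureCounts, with no version, and the genome build mm10 are named, per the submitters' processing notes. The annotation release was not given in the sources used here. Of 55416 gene IDs, 52083 were matched by ID to a symbol from GENCODE M21 or RefSeq, and the 3333 unmatched IDs, which held at most 0.233% of counts in any tumor, stayed in the tests under their IDs. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10, matched by gene ID and counted from 1.

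The counting left some genes near 0. In every tumor the mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 held at most 2, 1 and 4 counts, where mt-Co1 held at least 49575. Levels of genes with near-identical copies elsewhere in the genome, and of overlapping or antisense genes, are therefore uncertain in these counts. This applies to antibody variable segments (Ighv, Igkv), H2-T24, H2-Q6 and H2-Q7, and the Ifi20x, Oas and Slfn genes.

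Total counts ran from 13492254 to 67953936 per tumor, so the vaccine libraries and the shallower untreated ones limited the precision for genes of low abundance. The number of tumors limited the precision of every group mean. No tumors had identical counts, and the correlation of log2 CPM between tumors ran from 0.933 to 0.982. The labels give no batch.

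Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 with its default settings (16007 of 32062 genes with a count), library sizes were scaled by TMM, and groups were compared by the robust quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) with no covariate. P was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Log2 CPM for scores and plots used a prior count of 2. The median log2 fold change of all tested genes was -0.01 with TMM, -0.005 with RLE and -0.02 with upper quartile factors.

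Gene lists for 38 pathways, cell types and tissue admixtures were tested by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, two-sided, with adjustment over the lists. Camera asks whether a list moves more than other genes, and its preset correlation makes p too small where genes of a list vary together between tumors, so p with an estimated correlation is given too. Fry asks whether the genes of a list move, on balance, one way. Within each list, genes were also counted after adjustment over the list alone. A list score was the mean log2 CPM of its tested genes in a tumor. Scores were compared by an exact permutation test, two-sided, of the difference of group means over all 35 splits of the 7 tumors, whose smallest p is 0.0286. Adjusted over the 38 lists, no score difference reached 0.05 (lowest adjusted permutation p = 0.109).

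Named genes followed 3 rules. The first took genes past the threshold with a mean of at least 1 CPM, a proper gene name and every vaccine tumor on one side of every untreated tumor, up to 10 per direction by fold change. Where fewer than 10 passed, those next by p were added up to 10 in all and at most 5. The second took the 3 genes with the smallest p in the list's direction from each of the 8 called lists with the smallest p. The third always took Tgfb1, Tgfb2, Tgfb3, Acta2, Col1a1, Cd3e, Cd8a, Foxp3, Gzmb, Ifng, Cd274, Arg1, Nos2, Mrc1, Cd68 and Krt19. Further list members are given as examples and were chosen after their values were seen. The tests, lists, naming rules and alternatives were set before the data were examined, except those said to have been added later.

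Alternatives were DESeq2 1.42.0, limma voom with and without sample quality weights, RLE and upper quartile factors, no filter on low counts, a minimum mean count of 10, a threshold of 0.1, each tumor left out in turn, mouse number as a block, and other forms of the scores. Added after the data were seen were the muscle score as a covariate, a fit without the 3 untreated tumors that held muscle transcripts, and counts thinned to the shallowest library. The covariate fit rests on untreated 3 as the only untreated tumor with few muscle transcripts. The fit without the muscle tumors has that tumor as its only untreated one (n = 1), assumed to vary like the vaccine tumors.

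The scripts were tested on simulated data for the comparison of vaccine and untreated tumors, with 16007 genes drawn from the real means and library sizes. Of genes changed 2-fold 73% were recovered and of genes changed 4-fold 95%, with 15 false calls, or 8.20% of calls. The changed genes were drawn only from those of higher mean count, so recovery at low counts was not tested. Each gene was drawn on its own, with a spread estimated from the real tumors. The joint variation of genes, such as the muscle transcripts that set some untreated tumors apart, was therefore not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.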

Results

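Subcutaneous tumors of Pan02, a mouse pancreatic ductal adenocarcinoma cell line, were profiled by bulk poly(A) RNA sequencing in female C57BL/6 mice. The cells had been injected under the skin of the right flank. One group of 4 mice was left untreated. The other group of 3 mice was given peptides derived from transforming growth factor beta (TGF-beta), mixed with the adjuvant Montanide, on days 10 and 17. All 7 tumors were taken on day 30, and each library came from a separate animal. The untreated mice are not described as having received the adjuvant alone, so the comparison covers peptides and adjuvant together. The untreated libraries held 18808884, 26658448, 67953936 and 27416946 counts (mice 1 to 4), and the vaccine libraries 13492254, 20120836 and 15352346 (mice 1 to 3). A tumor is named below by its group and mouse number, and expression in CPM (the usual counts-per-million unit, on TMM-scaled libraries) is given as mean ± SD over the tumors of a group.

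The single comparison of the design asked how the tumor transcriptome differed after vaccination. In vaccine tumors, 7 of 16007 tested genes were higher and 1 was lower. The higher genes were antiviral interferon-induced genes (Rsad2, Oas2, Usp18), genes of B lineage cells (Cd79a, a chain of the B cell receptor complex, and the antibody variable segment Ighv1-53) and the non-classical MHC class I gene H2-T24. The lower gene was Jph2, which encodes a junctophilin of striated muscle. Every vaccine tumor lay above every untreated tumor for each of the higher genes, and below for Jph2.

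Ighv1-53 (ENSMUSG00000093894, chromosome 12, 115158403 to 115158835, minus strand, GRCm38) rose from 0.982 ± 0.497 to 11.1 ± 1.42 CPM (SD, n = 4 and 3), a log2 fold change of 3.53 ± 0.35 (SE; edgeR quasi-likelihood test, adjusted p = 0.0219). Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197, plus strand) rose from 1.89 ± 0.206 to 8.47 ± 2.48 CPM, or 2.17 ± 0.23 on the log2 scale (edgeR adjusted p = 0.0339). Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452, minus strand) rose 3.09-fold, from 13.7 ± 1.66 to 42.5 ± 8.26 CPM (edgeR adjusted p = 0.0219). Oas2 (ENSMUSG00000032690, chromosome 5, 120730333 to 120749853, minus strand) rose 2.86-fold, from 24.9 ± 4.50 to 71.4 ± 8.25 CPM (edgeR adjusted p = 0.0219). Usp18 (ENSMUSG00000030107, chromosome 6, 121245906 to 121270917, plus strand) rose 2.76-fold, from 13.1 ± 1.85 to 36.2 ± 7.68 CPM (edgeR adjusted p = 0.0366). H2-T24 (ENSMUSG00000053835, chromosome 17, 36005695 to 36020560, minus strand) rose 2.72-fold, from 13.8 ± 1.44 to 37.5 ± 9.13 CPM (edgeR adjusted p = 0.0366). Jph2 (ENSMUSG00000017817, chromosome 2, 163336242 to 163397993, minus strand) fell from 35.2 ± 4.92 to 15.1 ± 1.36 CPM, a log2 fold change of -1.22 ± 0.13 (edgeR adjusted p = 0.0359). In untreated 3, which lacked the skeletal muscle transcripts described below, Jph2 was 28.3 CPM, against 13.7 to 16.5 CPM in vaccine tumors. The remaining higher gene, Gm20559, is a processed transcript without a gene name and was outside the rule for named genes. It is named here after its values were seen, at 0.84 ± 0.08 on the log2 scale. Ighv1-53 and H2-T24 belong to families of near-identical genes, among which reads could have been split, so their own levels are uncertain.

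The next genes by p in each direction, separated in the same way but not past the threshold, were Ifi206 (log2 fold change 2.19 ± 0.26), BC147527 (1.75 ± 0.22), the B cell receptor gene Cd79b (1.13 ± 0.15) and the lipopolysaccharide-inactivating enzyme gene Aoah (0.92 ± 0.12) on the higher side. On the lower side these were the smooth muscle actin gene Acta2 (-1.02 ± 0.13), Serinc2 (-1.06 ± 0.14), the Hippo pathway transcription factor gene Tead2 (-0.58 ± 0.09), the muscle acetylcholine receptor gene Chrna1 (-2.56 ± 0.38) and the netrin receptor gene Unc5b (-0.50 ± 0.07), with edgeR adjusted p from 0.0516 to 0.0657 over these 9 genes. At an unadjusted p below 0.05, 1540 genes were higher and 1248 lower. The vaccine tumors lay apart from all untreated tumors for 2499 genes, or 15.6% of those tested, against 5.71% by chance. Untreated 1, 2 and 4, which held muscle transcripts, lay apart from the other 4 tumors for 2354 genes. The count of changed genes depended on the tool and on single tumors: DESeq2 called 725 higher and 425 lower, limma voom called 5 higher and 0 lower, and edgeR called 1, 0, 472 and 0 genes without untreated 1, 2, 3 and 4, and 1, 61 and 2 without vaccine 1, 2 and 3. With the muscle transcripts described below as a covariate, edgeR called 0 genes, with 772 at an unadjusted p below 0.05. In that fit Ighv1-53 was 3.95 ± 0.54 (3.53 ± 0.35 without the covariate), Cd79a 2.18 ± 0.41 (2.17 ± 0.23), Rsad2 1.51 ± 0.24 (1.63 ± 0.15), Usp18 1.36 ± 0.26 (1.47 ± 0.17) and H2-T24 1.34 ± 0.26 (1.44 ± 0.17), so that these calls ended mainly with larger standard errors. Oas2 at 1.27 ± 0.19 (1.52 ± 0.15) and Jph2 at -0.94 ± 0.14 (-1.22 ± 0.13) also had smaller fold changes.

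**Figure D1:**
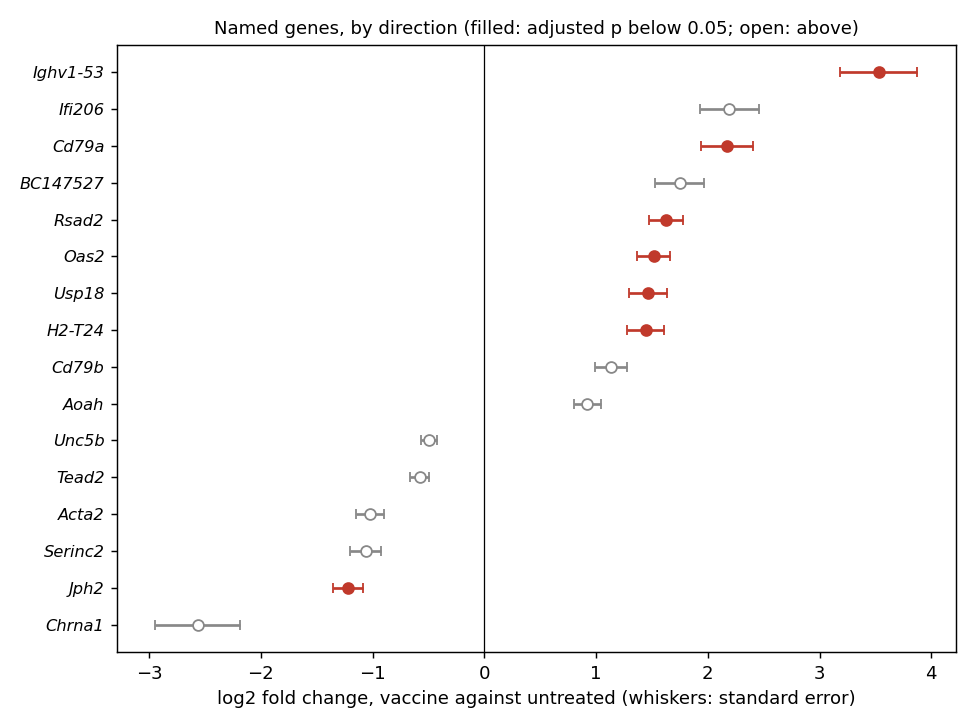
Log2 fold changes (x axis, vaccine against untreated, with standard errors as whiskers) of the 16 named genes that separated the groups, the 10 higher and 6 lower genes taken by the naming rule in each direction, without Gm20559. Filled points mark the genes past an adjusted p of 0.05, from Ighv1-53 at 3.53 to Jph2 at -1.22, and open points those that were not.

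The type I interferon response stood out among the 38 gene lists fixed beforehand. All 28 tested members of the list were higher in vaccine tumors, with a median log2 fold change of 1.32 and a range of 0.59 to 1.87, and all 28 rose when p was adjusted over the list alone. Over all genes tested, 3 of them rose (Rsad2, Oas2, Usp18). Other members included Irf7, the transcription factor that amplifies interferon production (67.5 to 238 mean CPM), the oligoadenylate synthetase gene Oas3 (log2 fold change 1.87 ± 0.27), the ubiquitin-like modifier gene Isg15 (1.38 ± 0.28) and the antiviral GTPase gene Mx1 (1.24 ± 0.18). The score of the list, its mean log2 CPM, was 4.84 ± 0.19 in untreated and 6.12 ± 0.35 in vaccine tumors (SD, n = 4 and 3), a difference of 1.28 (exact two-sided permutation p = 0.0286, the smallest that 35 splits allow). The list was called by camera with a preset correlation (adjusted p = 2.07e-66) and by fry (adjusted p = 0.0216), but not by camera with an estimated correlation (adjusted p = 0.0843). With the muscle score as a covariate the median was 1.12, and 23 members rose over the list alone.

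Genes of B cells and plasma cells rose. Over the list alone 9 of 14 tested B cell genes rose, among them Cd79a, Cd79b, the surface marker Ms4a1 (CD20; log2 fold change 2.33 ± 0.34) and the IgM heavy-chain gene Ighm (4.22 ± 0.83). Over all genes tested this was 1 gene, Cd79a. Of 16 plasma cell genes, 12 rose over the list alone and 0 over all genes tested. They included Mzb1, a chaperone of antibody-secreting cells (3.22 ± 0.55), the survival receptor gene Tnfrsf17 (2.76 ± 0.56), the joining chain gene Jchain (3.42 ± 0.71), the kappa constant gene Igkc (3.41 ± 0.65) and Xbp1, the secretory transcription factor (0.43 ± 0.08). Against that direction, Sdc1, which epithelial cells also express, fell by 0.45 ± 0.16 over the list alone. The median log2 fold change was 1.09 for the B cell list and 2.48 for the plasma cell list, and every vaccine tumor scored above every untreated tumor for both (exact permutation p = 0.0286 each). The B cell score was 2.09 ± 0.07 in untreated and 3.29 ± 0.45 in vaccine tumors, and the plasma cell score 3.89 ± 0.62 and 6.15 ± 0.92. Both lists were called by camera with the preset correlation (adjusted p = 7.62e-15 and 4.99e-16). With an estimated correlation neither was (camera adjusted p = 0.122 for each), and fry called the B cell list (adjusted p = 0.0318) but not the plasma cell list (adjusted p = 0.0506). With the muscle score as a covariate the medians were 1.00 and 2.51, and 3 B cell and 0 plasma cell genes rose over the list alone.

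Monocyte and macrophage markers were higher in vaccine tumors for all 20 tested members, with a median log2 fold change of 0.63. Over the list alone 15 rose, and over all genes tested 0. Examples were Ly6c2 (3.26 ± 0.50), the Fc receptor gene Fcgr1 (1.22 ± 0.23), the efferocytosis receptor gene Mertk (0.63 ± 0.11), the macrophage surface marker Adgre1 (0.78 ± 0.16) and Cd68 (0.71 ± 0.22, with 167 ± 33.2 and 273 ± 69.5 CPM, SD, n = 4 and 3). Ly6c2 had the largest rise of the list, while Ccr2 (0.26 ± 0.26) did not rise over the list alone. Of 18 M1-like genes 10 rose over the list alone, with a median of 0.65, including Cd40 (0.69 ± 0.18), Tnf (0.98 ± 0.32) and the nitric oxide synthase gene Nos2 (1.07 ± 0.34). None of the 21 M2-like genes rose over the list alone (median 0.23), and Mrc1 (0.56 ± 0.27) and Arg1 (0.21 ± 0.60) were not past the threshold. The M1-like minus M2-like score was -1.26 ± 0.44 in untreated and -1.08 ± 0.26 in vaccine tumors, which differed by less than the spread (difference 0.19, exact permutation p = 0.686). Camera with the preset correlation called all 3 lists (adjusted p = 1.09e-20 for the markers, 1.69e-07 for M1-like and 0.00241 for M2-like genes). With an estimated correlation camera called none of them (adjusted p = 0.122, 0.0843 and 0.325), while fry called the markers (adjusted p = 0.0318) and the M1-like genes (adjusted p = 0.0216). The marker and M1-like medians were 0.49 and 0.39 with the muscle score as a covariate, and 0 genes of either list rose over the list alone. Dendritic cell markers had a median of 0.56, and 4 of 18 rose over the list alone: Irf8, Xcr1 and Wdfy4, genes of cross-presenting dendritic cells, and Bst2. That list was called by camera with the preset correlation (adjusted p = 2.76e-06), with adjusted p = 0.325 with an estimated correlation. The marker and M1-like scores separated the groups (exact permutation p = 0.0286 each), the M2-like and dendritic cell scores did not (exact permutation p = 0.143 and 0.0857).

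Antigen presentation genes were higher. All 21 MHC class I genes had positive log2 fold changes (median 0.52), and 11 rose over the list alone but 0 over all genes tested. Beta-2 microglobulin (B2m), the shared light chain of these molecules, was 1762 ± 208 CPM in untreated and 2800 ± 314 CPM in vaccine tumors (0.67 ± 0.13 on the log2 scale). H2-Q7 (0.90 ± 0.18) and H2-Q6 (0.82 ± 0.21) rose too over the list alone, although reads could have been split among these near-identical genes. With the muscle score as a covariate these were lower, at 0.50 ± 0.15 and 0.38 ± 0.20, and 0 members of the list rose. Of 13 MHC class II genes, 2 rose over the list alone, H2-Ob and the protease gene Ctss, with a median of 0.53. The interferon-gamma response list was higher in all 27 members (median 0.66), of which 1 rose over the list alone, Cd274, the gene of the checkpoint ligand PD-L1 (0.69 ± 0.13). Cxcl11 (1.26 ± 0.34) and Serpina3g (0.96 ± 0.28) did not pass within this list, although Cxcl11 rose within the M1-like list. Cxcl11 is annotated as a polymorphic pseudogene and was low, at 0.596 ± 0.219 CPM in untreated and 1.46 ± 0.181 CPM in vaccine tumors. The interferon-gamma score was 5.84 ± 0.19 in untreated and 6.39 ± 0.66 in vaccine tumors and did not separate them (exact permutation p = 0.229), as vaccine 2 lay at 5.68, level with the lowest untreated tumor. The class I score separated the groups (exact permutation p = 0.0286) and the class II score did not (exact permutation p = 0.0571). The class II score was 8.48 in vaccine 1, against 7.68 and 7.93 in vaccine 2 and 3 and at most 7.69 in untreated tumors. The interferon-gamma score was 6.98 in vaccine 1 and 6.53 in vaccine 3, so vaccine 1 was highest for both. Camera with the preset correlation called the class I, class II and interferon-gamma lists (adjusted p = 1.79e-12, 1.19e-06 and 4.51e-10), and with an estimated correlation none (camera adjusted p = 0.302, 0.302 and 0.325). Their medians were 0.46, 0.42 and 0.63 with the muscle score as a covariate.

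Of 22 CD8 T cell and cytotoxicity genes, 20 had positive log2 fold changes (median 0.57), and 1 rose over the list alone, the granule protein gene Nkg7 (0.89 ± 0.20). Cd8a (0.71 ± 0.30), the granzyme gene Gzmb (0.87 ± 0.27) and Ifng (0.86 ± 0.46) were not past the threshold, and neither were Cd3e (0.36 ± 0.31) nor the regulatory T cell factor gene Foxp3 (0.01 ± 0.32). The CD8 list was called by camera with the preset correlation (adjusted p = 8.15e-05), not with an estimated correlation (camera adjusted p = 0.344), and not without vaccine 1 (camera adjusted p = 0.160). The pan T, T helper and regulatory T cell lists were not called (camera adjusted p = 0.164, 0.939 and 0.582), with medians of 0.20, -0.04 and 0.04, and the mean of the T helper list was 0.06. Camera called the pan T cell list higher without untreated 3 or vaccine 3 (adjusted p = 0.0304 and 0.00620). Against untreated 3 alone (n = 1), without the untreated tumors with muscle transcripts, its median was -0.15. The CD8 median was 0.31, the pan T cell median -0.05 and the checkpoint median 0.28 with the muscle score as a covariate. The CD8 minus regulatory T cell score was -1.60 ± 0.19 in untreated and -1.34 ± 0.22 in vaccine tumors (difference 0.26, exact permutation p = 0.2, 0.3 after adjustment over the 3 score contrasts). Of 16 checkpoint and exhaustion genes 5 rose over the list alone: Cd274, Entpd1, Vsir, Btla and Havcr2. The median of that list was 0.43 (camera adjusted p = 0.000335, and 0.325 with an estimated correlation). Neither the CD8 nor the checkpoint score separated the groups (exact permutation p = 0.0571 and 0.114). The checkpoint score was 4.46 in vaccine 1 but 3.79 and 3.92 in vaccine 2 and 3, against 3.60 to 3.91 in untreated tumors.

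**Figure D2:**
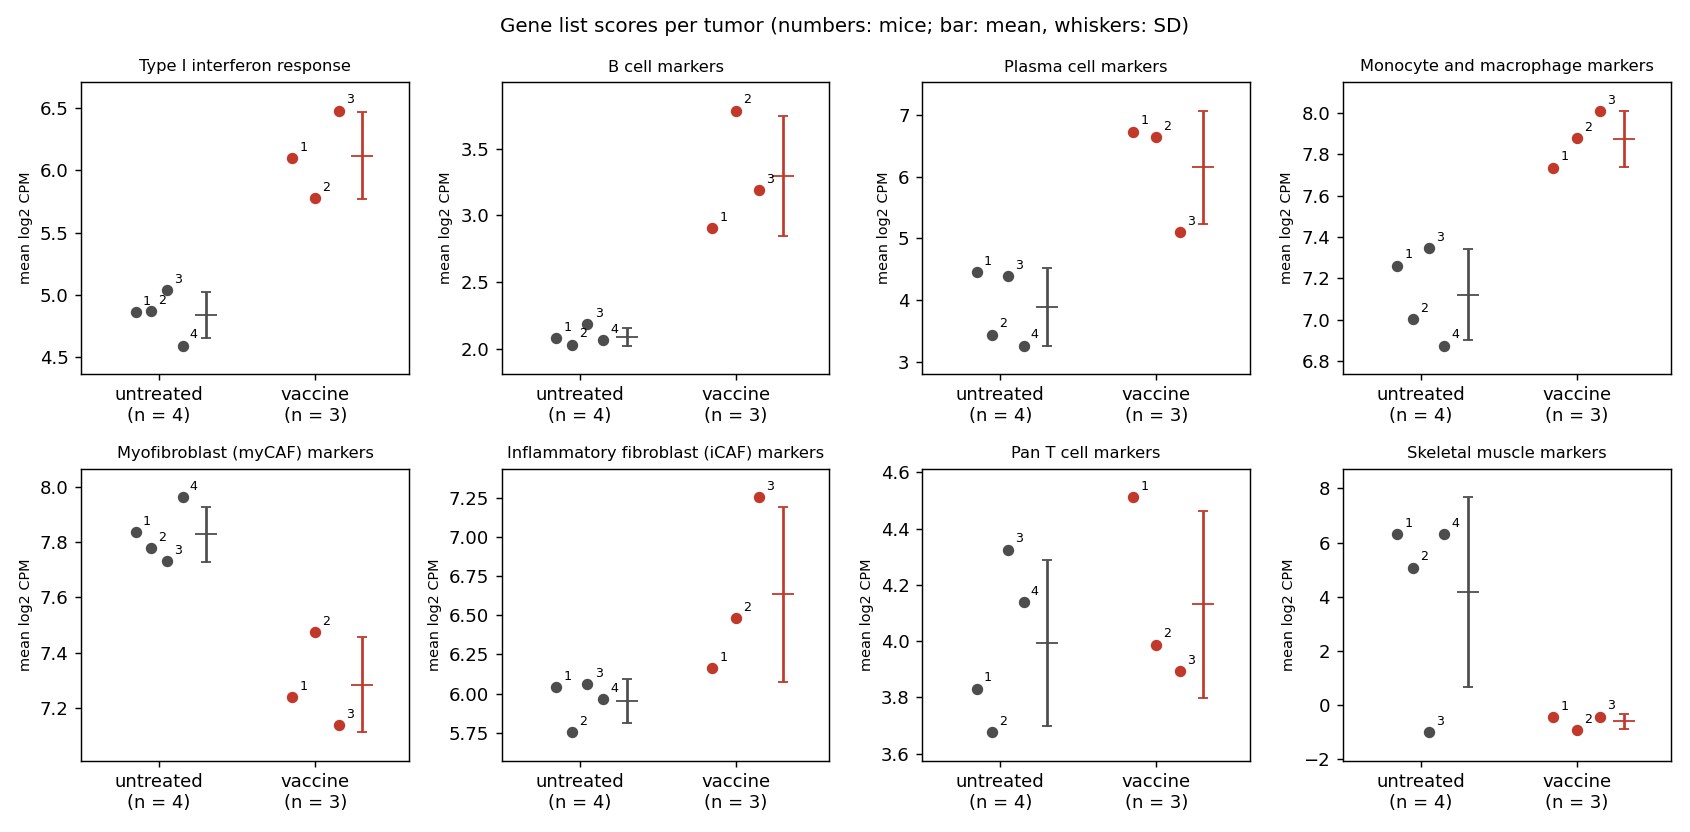
Mean log2 CPM (y axis) over 8 gene lists in each tumor, grey for the 4 untreated and red for the 3 vaccine tumors, numbered by mouse, with the group mean and SD beside the points. The vaccine tumors lay above all untreated tumors for the interferon, B cell, plasma cell, macrophage and iCAF lists and below them for the myCAF list, while the pan T cell scores overlapped and muscle markers were high in untreated 1, 2 and 4.

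The list of myofibroblastic fibroblast (myCAF) genes, which holds contractile and matrix genes, was lower in vaccine tumors, and that of inflammatory fibroblast (iCAF) genes was higher. Over the list alone 8 of 19 myCAF genes fell and 0 rose (median log2 fold change -0.57). Acta2 (chromosome 19, 34241090 to 34255590, minus strand), the usual myofibroblast marker, was 220 ± 28.4 CPM in untreated and 108 ± 13.1 CPM in vaccine tumors (SD, n = 4 and 3). It fell over the list alone, as did the contractile genes Tagln (-0.98 ± 0.17) and Myl9 (-0.91 ± 0.14) and the matrix gene Tnc (-0.95 ± 0.16). The contractile gene Cnn1 did not (0.09 ± 0.47), and the pericyte and smooth muscle list was not called (median -0.04, camera adjusted p = 0.0904). Over all genes tested these missed the threshold (edgeR adjusted p = 0.0516 for Acta2). In untreated 3, which lacked muscle transcripts, Acta2 was 206 CPM. Of 21 iCAF genes, 19 had positive log2 fold changes (median 0.71), and 4 rose over the list alone: the complement gene C3 (0.71 ± 0.15), Pi16 (1.76 ± 0.45) and the chemokine genes Ccl2 (1.09 ± 0.30) and Ccl7 (1.29 ± 0.35). The iCAF score was 6.16, 6.48 and 7.25 in vaccine 1, 2 and 3 and at most 6.06 in untreated tumors, so the rise was largest in vaccine 3. The myCAF minus iCAF score was 1.87 ± 0.17 in untreated and 0.65 ± 0.66 in vaccine tumors, with all vaccine tumors below all untreated tumors (difference -1.22, exact permutation p = 0.0286, 0.0857 after adjustment over the 3 score contrasts). Camera with the preset correlation called both lists (adjusted p = 1.97e-11 and 5.35e-09). With an estimated correlation it called neither (adjusted p = 0.0843 and 0.302), and fry called the myCAF list (adjusted p = 0.0216). With the muscle score as a covariate the myCAF median was -0.38, with 5 genes lower over the list alone, and the iCAF median 0.71, with 0.

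Of the vaccine's target pathway, the TGF-beta response score was lower in every vaccine tumor than in every untreated tumor (6.35 ± 0.04 in untreated and 6.13 ± 0.13 in vaccine tumors, SD, n = 4 and 3, difference -0.23, exact permutation p = 0.0286, 0.109 after adjustment over the 38 lists). The ligand genes Tgfb1 (0.07 ± 0.07), Tgfb2 (-0.36 ± 0.24) and Tgfb3 (-0.49 ± 0.26) were not past the threshold. Tgfb2 was -0.77 ± 0.23 with the muscle score as a covariate and -0.82 ± 0.28 against untreated 3 alone (n = 1), again not past the threshold. The collagen gene Col1a1 was not past it either (20223 ± 3983 and 17969 ± 1861 CPM, log2 fold change -0.17 ± 0.18). Of 22 TGF-beta response genes, 19 had negative log2 fold changes with a median of -0.16, and 0 fell over the list alone. Col7a1 (-1.14 ± 0.46), Ltbp2 (-1.03 ± 0.51), Id1 (-0.36 ± 0.13), Smad7 (-0.20 ± 0.10) and Pmepa1 (-0.20 ± 0.10) were among them, and the median was -0.11 with the muscle score as a covariate. The list was called by camera with the preset correlation (adjusted p = 0.0141), but not with an estimated correlation (camera adjusted p = 0.325) and not without untreated 3 or vaccine 1 (camera adjusted p = 0.0587 and 0.158). The list of ligands, activators and receptors was not called (camera adjusted p = 0.292). The collagen and matrix list had 19 of 30 genes lower with a median of -0.14 (camera adjusted p = 0.0424, and 0.536 with an estimated correlation). It was not called without untreated 3 or 4 or vaccine 1 (camera adjusted p = 0.465, 0.0902 and 0.396).

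Skeletal muscle transcripts marked 3 of the 4 untreated tumors. Acta1, the skeletal muscle actin gene, was 867, 293 and 714 CPM in untreated 1, 2 and 4, against 0.234 CPM in untreated 3 and 0.973, 0.606 and 1.47 CPM in the vaccine tumors. The muscle list held 0.327%, 0.125% and 0.285% of counts in untreated 1, 2 and 4 and at most 0.00902% in the other tumors. All 21 tested muscle genes had negative log2 fold changes (median -7.14, or -6.43 with the 1 gene without a count in any vaccine tumor set at 3 counts), and 19 fell over the list alone. Myl1 (-8.59 ± 2.47), Tnnt3 (-7.14 ± 2.06) and Eno3 (-1.30 ± 0.32) were the members with the smallest p. Camera called the list with the preset correlation (adjusted p = 1.19e-19) but not with an estimated correlation (adjusted p = 0.302), and its score did not separate the groups (exact permutation p = 0.143). Skin keratinocyte genes such as Krt5 and Krt14 had a median of -4.08 and adipocyte genes of -1.35, and 0 of either list fell over the list alone. Camera with the preset correlation called both (adjusted p = 1.22e-08 and 0.00175), and with an estimated correlation neither (adjusted p = 0.325 and 0.513). The first principal component, with 51.9% of the variance, placed untreated 1, 2 and 4 at -46.8, -45.6 and -60.7. Untreated 3 lay at 20.8 and the vaccine tumors at 43.8, 45.6 and 42.8.

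**Figure D3:**
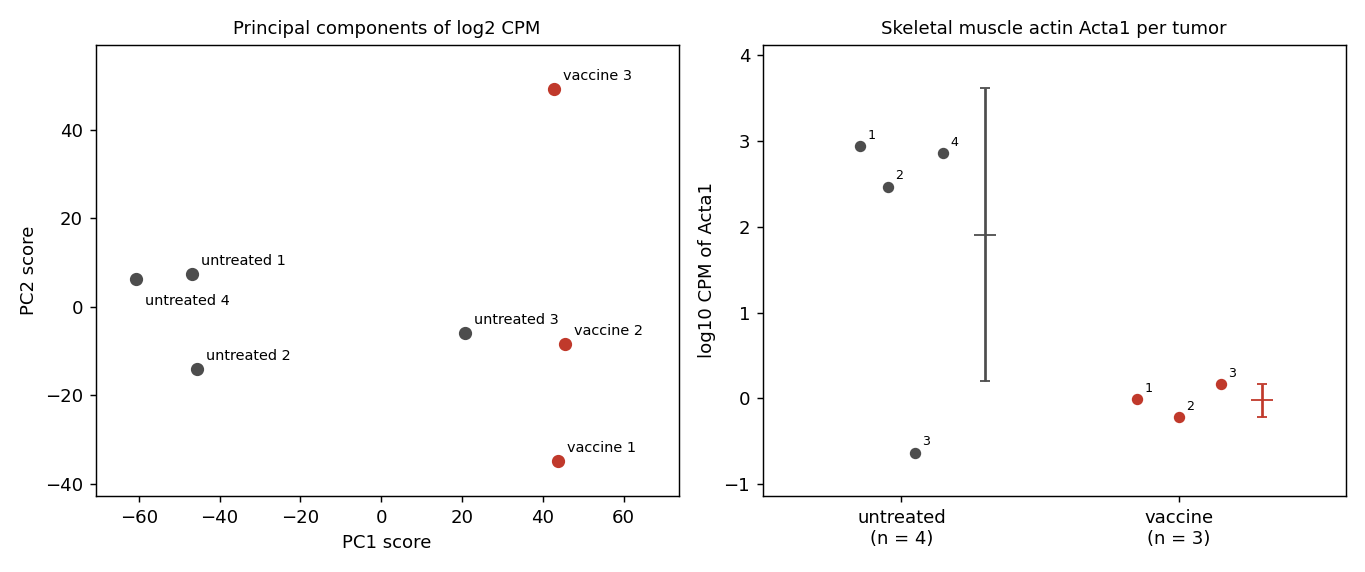
Left, the first 2 principal components of log2 CPM (scores, no unit) for the 4 untreated (grey) and 3 vaccine tumors (red). Right, log10 CPM of the skeletal muscle actin gene Acta1 in each tumor with the group mean and SD. Untreated 3, at 0.234 CPM of Acta1, lay on the side of the vaccine tumors.

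Of the remaining lists, the epithelial and ductal tumor cell list had 12 of 17 genes lower. Its median was -0.34, but -0.09 with the muscle score as a covariate and -0.07 against untreated 3 alone (n = 1), with Krt19 at 374 ± 93.9 and 294 ± 17.4 CPM, which was not past the threshold. Proliferation genes were lower in 28 of 30 (median -0.16), including Mcm2 (-0.25 ± 0.09) and Top2a (-0.30 ± 0.11), and 0 of them or of the epithelial list fell over the list alone. The proliferation score was 5.02 in vaccine 2, while vaccine 1 and 3 (5.42 and 5.38) lay within the untreated range of 5.29 to 5.54. Its difference had an exact permutation p of 0.314, and camera with an estimated correlation gave an adjusted p of 0.536. Globin genes Hbb-bs, Hbb-bt and Hba-a1 and the heme synthesis gene Alas2 rose over the list alone, at 4 of 5 erythroid genes (median 2.35). The erythroid score was 1.35, 2.71 and 3.92 in vaccine 1, 2 and 3, and 1.36 in untreated 3. It did not separate the groups (exact permutation p = 0.0571), and camera with an estimated correlation did not call the list (adjusted p = 0.302). In the mast cell, basophil and eosinophil list Il5ra (2.41 ± 0.47) and Prg2 (1.86 ± 0.40) rose over the list alone. Both were low, at means of 0.576 and 2.99 CPM for Il5ra and 0.393 and 1.45 CPM for Prg2. The eosinophil genes Siglecf (0.92 ± 0.59) and Ccr3 (0.11 ± 0.30) did not rise over the list alone, and Epx was below the filter. In the mesothelial and antigen-presenting fibroblast list Saa3 (1.36 ± 0.33) and Slpi (2.61 ± 0.69) rose over the list alone. In all, camera with the preset correlation called 22 lists higher and 11 lower, with an estimated correlation it called 0, and fry called 5: the type I interferon, macrophage, M1-like, B cell and myCAF lists. The muscle, skin and adipocyte medians were -0.14, -0.19 and -0.22 with the muscle score as a covariate.

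**Figure D4:**
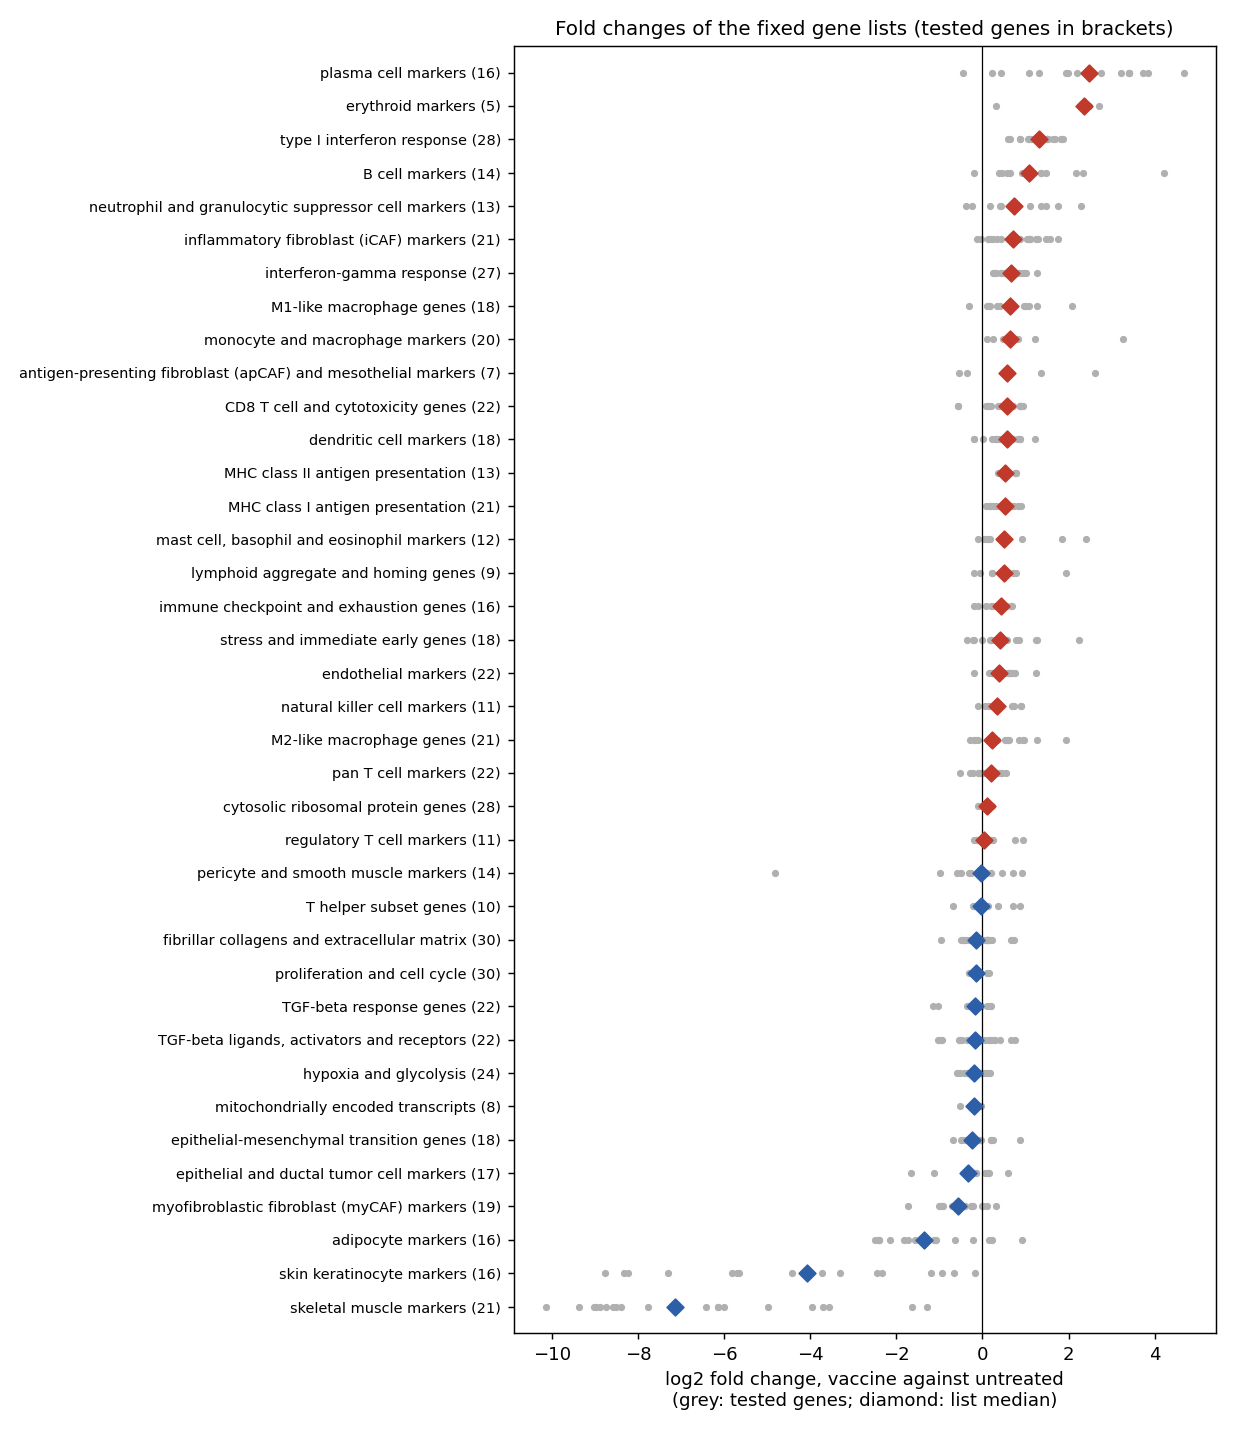
Log2 fold changes (x axis, vaccine against untreated) of the tested genes of each of the 38 lists (grey points) and the list medians (diamonds, red above 0 and blue below), ordered by median. Medians ran from -7.14 for skeletal muscle to 2.48 for plasma cell markers, and all 28 type I interferon genes lay above 0.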

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

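The comparisons of scores in this part, except the planned myCAF minus iCAF score, were chosen after the results had been seen, and 2 of them replaced comparisons that had missed. Of 92 values tested within the untreated group for a tumor far from the other 3, 6 were found, where chance expects 4.6. Untreated 2 scored 2.11 for lymphoid aggregate genes (others 2.60 to 2.69) and -1.31 for the CD8 minus regulatory T cell score (others -1.72 to -1.66). Untreated 3 scored -1.004 for skeletal muscle markers (others 5.08 to 6.32), and its log2 CPM of Serpina3g was 4.80 (others 4.35 to 4.37). Untreated 1 scored 9.03 for mitochondrial transcripts (others 9.18 to 9.21), and in untreated 4 log2 CPM of Tgfb1 was 7.64 (others 7.74 to 7.74).

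Chance in the assignment of tumors cannot be excluded for the count of changed genes, since 2 of 35 splits gave at least the real count of 8. The highest count, 267, set untreated 1, 2 and 4 against the other tumors, which points to a structure of the samples along the muscle transcripts. For gene lists called, only the real split (1 of 35) gave 33, and the highest other split gave 28. The lowest gave 13, so camera with the preset correlation called many lists for any grouping of these tumors. After thinning all libraries to the shallowest, 10 genes changed, the 8 among them, so these calls did not need unequal depth. As thinning keeps the expected share of each gene, it cannot decide on other effects of library depth.

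Type I interferon genes were higher in vaccine tumors, with a list median log2 fold change of 1.32. Muscle tissue in untreated tumors is argued against by the median of 1.12 with the muscle score as a covariate. That fit rests on untreated 3 as the only untreated tumor with few muscle transcripts. The interferon score of untreated 3 was 5.04, against 6.10, 5.78 and 6.48 in vaccine 1, 2 and 3. After thinning the list median was 1.35. Thinning keeps the expected share of each gene in a library, so this value cannot decide on library depth. A larger share of macrophages stays open. The interferon minus macrophage score was higher by 0.53 (exact permutation p = 0.0286), but this lay below 0.5 of the interferon score difference of 1.28, the bound set for that explanation. An interferon response to the vaccine or to its adjuvant also stays open, and the design does not separate these.

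B cell and plasma cell lists were higher in vaccine tumors. An equal rise of all lymphocytes is argued against by the scores themselves. These were higher in vaccine tumors by 1.20 for B cell, 2.26 for plasma cell and 0.14 for pan T cell genes. A lower share of tumor cells would raise all other cell types alike, so these scores argue against it as the only cause. A part from it stays open. Macrophage, dendritic cell and endothelial scores were higher by 0.75, 0.49 and 0.38, and the epithelial score was lower by 0.27. The myCAF score and the pericyte and smooth muscle score were lower too, by 0.54 and 0.41. The mean of the B and plasma cell scores minus the pan T cell score was higher by 1.596 (exact permutation p = 0.0286). It was built from scores already seen to differ, so its p is no separate support. This comparison replaced the plasma cell minus endothelial score, which had missed at 1.88 (exact permutation p = 0.0571). For a small piece of lymph node the same 1.596 decides nothing: the pan T cell score of untreated tumors was above that of B cell genes (3.99 against 2.09), where a small gain shows less, and for plasma cell genes, which started near it (3.89), the tables hold no profile of such a piece. Of 9 tested lymphoid aggregate and homing genes, 7 were higher (median log2 fold change 0.50) and 0 rose over the list alone. Their score did not separate the groups (exact permutation p = 0.229). The B cell genes Cr2 and Fcer2a and the homing genes Glycam1, Madcam1 and Chst4 were below the filter. These values show no clear gain of such tissue, but a small piece of lymph node, follicles rich in B cells and an effect of the adjuvant stay open.

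The myCAF list was lower in vaccine tumors. Muscle tissue in untreated tumors may account for part of it, as the median was -0.38 with the muscle score as a covariate against -0.57 without. Fewer fibroblasts overall would lower both fibroblast lists, but the myCAF score was lower by 0.54 and the iCAF score higher by 0.68. These values argue against it as the only cause, although the iCAF list holds genes that other cells express, such as Ccl2 and C3. The myCAF minus iCAF score was lower by 1.22 (exact permutation p = 0.0286, 0.0857 after adjustment over the 3 score contrasts). As each score had already separated the groups, this p is no separate support. The myCAF minus collagen and matrix score, tried first, had missed at -0.44 (exact permutation p = 0.0571). Whether fibroblasts or tumor cells lost Acta2 stays open.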

How the results depend on the processing

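The muscle covariate, the fit without the untreated tumors that held muscle and the thinned counts were chosen after the results had been seen, and the other settings before the data were examined. With 3 and 4 tumors no score can pass once a tumor is left out, as the smallest exact permutation p is then 0.1 or 0.0667. The cause of the differences between settings was not tested. Against 8 changed genes (7 higher, 1 lower), an adjusted p below 0.1 gave 304 (246 and 58), DESeq2 1150 (725 and 425), limma voom 5 (5 and 0) with or without sample quality weights, no low-count filter 265 (200 and 65), and upper quartile factors and thinning 10 each (8 and 2). With the muscle score as a covariate, and without the 3 untreated tumors with muscle transcripts, 0 were called (0 and 0). The latter fit sets 3 vaccine tumors against untreated 3 alone (n = 1), which is assumed to vary as they do, so its directions rest on that tumor. Cd79a (2.17) was 2.18 and 2.23 in these fits, Rsad2 (1.63) 1.51 and 1.48, Ighv1-53 (3.53) 3.95 and 3.88, and Jph2 (-1.22) -0.94 and -0.91. Leaving out one tumor gave 0 to 472 (0 to 249 higher, 0 to 223 lower). Mouse numbers name different animals and do not pair them (correlations of -0.003, -0.07 and -0.03 between equal numbers). With mouse number as a replicate block 5 genes were called (4 and 1), the matrix list had a camera adjusted p of 0.187, and Arg1 was -0.36.

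Camera with an estimated correlation called 0 lists, with adjusted p = 0.0843 for myCAF and type I interferon, 0.122 for B cell, plasma cell and macrophage, 0.302 for MHC class I and skeletal muscle, 0.325 for TGF-beta response, 0.344 for CD8 and 0.536 for matrix genes. Fry called 5, with adjusted p = 0.0506 for plasma cell, 0.158 for TGF-beta response and MHC class I, 0.171 for CD8 and skeletal muscle, and 0.372 for matrix genes. Leaving out one tumor, camera adjusted p ran from 0.00175 to 0.465 for matrix, 0.00182 to 0.158 for TGF-beta response and 3.5e-07 to 0.160 for CD8 genes. The skeletal muscle list had a camera adjusted p of 0.440 with the covariate and 0.185 against untreated 3 alone, both in the other direction. Against untreated 3 alone (n = 1) the pan T cell and lymphoid aggregate lists lay lower (camera adjusted p = 0.0143 and 0.651), Tnnt3 was 0.43 and Foxp3 -0.24. Foxp3 was -0.0758 and Arg1 -0.10 with limma voom, and -0.14 and -0.0132 with the covariate. Leaving out one tumor, log2 fold changes ran from -0.34 to 0.23 for Foxp3, -0.88 to 0.59 for Arg1, -0.0413 to 0.64 for Cd3e and -0.0116 to 1.20 for Ifng, the lowest without vaccine 1 except for Arg1, which was lowest without vaccine 2. The camera adjusted p of the stress list ran from 6.3e-09 to 0.695, and that list was lower without vaccine 3. The myCAF minus iCAF score ran from -1.44 to -0.84, and the M1-like minus M2-like score from -0.0333 (without untreated 1) to 0.30.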

Other observations

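The gene families and the Ly6c2 comparison in this part were chosen after the results had been seen, and 12 families were examined, over which p was adjusted. As the families were picked from these same results, their p values are no separate support. Camera with an estimated correlation called 0 of the 38 lists fixed beforehand. All 13 tested PYHIN genes, a family of nucleic acid sensors and interferon-induced nuclear proteins, were higher in vaccine tumors (median log2 fold change 1.27). Of these 12 rose when adjusted over the family alone, including Ifi213, Ifi208 and Ifi206, while Aim2 did not. All 8 Schlafen genes were higher (median 0.94) and 7 rose over the family alone, among them Slfn4 and Slfn1. All 8 oligoadenylate synthetase genes rose (median 1.27), a family that shares members with the interferon list. Camera with an estimated correlation called each of these families (adjusted p = 0.0348). Guanylate-binding protein genes were higher in 11 of 11 (median 0.83) but were not called (camera adjusted p = 0.230 with an estimated correlation). Of them 0 rose over the family alone. Tripartite motif genes were 21 higher and 24 lower, of which 11 rose and 2 fell over the family alone, and histone genes 17 higher and 10 lower, of which 0 rose (camera adjusted p = 0.298 and 0.667 with an estimated correlation).

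Antibody variable segments were higher in 43 of 45 heavy-chain genes (median 3.47) and 53 of 56 kappa genes (median 2.99), of which 8 and 16 rose over the family alone. Both had adjusted p = 0.0348 by camera with an estimated correlation. All 3 lambda genes were higher, with the same camera adjusted p. That family is below the minimum of 4 tested genes set for a list test, so its p is not counted as a call. Of CC chemokine genes 16 of 19 were higher (median 0.68), and 7 rose over the family alone, including Ccl3, Ccl4, Ccl8 and Ccl12. Of CXC chemokine genes 12 of 13 were higher (median 0.69), and 0 rose over the family alone. All 10 H2-T and H2-Q genes were higher (median 0.63), and 8 rose over the family alone. Camera with an estimated correlation called these 3 families (adjusted p = 0.0348 for CC chemokine, 0.0434 for CXC chemokine and 0.0348 for H2-T and H2-Q genes). Of 8 antibody shares tested, none passed after adjustment. The share of Ighm in heavy-chain constant counts was 38.8% ± 14.4% in untreated and 71.8% ± 20.5% in vaccine tumors (SD, n = 4 and 3, exact permutation p = 0.0857, 0.274 after adjustment over the 8 shares). The highest heavy-chain variable segment held 21.5% ± 10.7% and 21.5% ± 3.02% (exact permutation p = 0.971, the same after adjustment).

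More Ly6c-high monocytes as the only source of the higher Ly6c2 was tested against Ccr2, which these cells express. Log2 CPM of Ly6c2 minus that of Ccr2 was higher by 2.93 in vaccine tumors (exact permutation p = 0.0286), but Ccr2 started at 80.0 to 166 CPM in untreated tumors and Ly6c2 at 4.44 to 12.4 CPM. A gain of both genes from added monocytes would show less in Ccr2, so this explanation stays open.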
